A study of Mus musculus with 8 samples.

How the data were processed

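RNA from 8 mouse placentas was measured on 8 Agilent 1-colour (Cy3) expression arrays, 1 array per placenta, at 18.5 days post coitum. Per the labels, 4 placentas had fathers on a folate-sufficient diet (FS1 to FS4) and 4 had fathers on a folate-deficient diet (FD1 to FD4). Each placenta came from its own litter and its own father, so each counted as 1 replicate. The numbers 1 to 4 name placentas within a group, and nothing in the labels pairs them between groups.

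The deposited scanner files held spot intensity values for each array, which the scanner software had background-subtracted and spatially detrended, per the file headers. The software was Agilent Feature Extraction version 10.7.3.1, per the file headers, and no normalization between arrays had been applied to these intensities. Agilent Feature Extraction and limma are also named in the submitters' processing notes, with no version given in the sources used here. The authors' value table held log2 values whose columns had nearly equal quantiles, the largest gap over nearly the whole range being 0.0774. Its column medians were 5.52, 5.52, 5.53 and 5.53 in FS1 to FS4 and 5.53, 5.53, 5.53 and 5.50 in FD1 to FD4. All 55681 of its entries matched a probe name, and each column's deviations from the probe means correlated with those of its own array with r between 0.936 and 0.973 across probes. The exact steps behind that table are not given in the sources used here, and it served as an alternative source of values.

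Each array held 62976 spots, of which 59305 were not controls and represented 55681 probes. All 8 arrays were on 1 slide and scanned in 1 scan, so neither slide nor scan could act as a batch; both groups were present in each of the slide's rows. Control spots and spots with an outlier flag were left out, which removed at least 1 value of 67 probes, and no spot was saturated. The processed intensity was taken to log2, the 75th percentile of the array was subtracted, and spots of 1 probe were averaged. Levels are therefore log2 units relative to the array's 75th percentile, and differences are FD minus FS. Probes well above background on at least 4 of the 8 arrays, whatever the group, were tested, which kept 31208. A probe not well above background on any array of a group has only a bound there. In that case the fold is given as a background bound, the brighter group's mean over the dimmer group's mean. Each dim array is then set at the higher of the probe's own signal and the lowest signal well above background. The bound does not allow for sampling error.

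Probes were named by matching the accession in the file, without its version, to a RefSeq gene table of assembly GRCm38.p6. The arrays were annotated on mm9, so no coordinates are given. Of the probes, 26413 received 1 gene symbol, covering 20018 genes, and 29268 stayed unnamed; 16194 of these carry only a genomic position. H19 has no probe with a matched name and is not analysed here. Where a gene has several probes, the one with the highest mean signal stood for the gene in lists, and probes that disagree are mentioned.

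Groups were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes over all 8 placentas with no covariate and Benjamini-Hochberg adjustment. The results were the number of probes with an adjusted p under 0.05, and the number with an unadjusted p under 0.05 and a change of at least 1.5-fold. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with fry, and with an exact two-sided permutation test of the list's mean over the 70 relabellings. The smallest p that 70 relabellings can give is 0.0286. Lists with under 5 measured genes received no list test. Within-group spread was compared as the log2 ratio of median SDs over genes, FD over FS, with the same exact test. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

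There were 28 lists, of which 26 were tested. They covered spongiotrophoblast and glycogen cells, trophoblast giant cells, labyrinth syncytiotrophoblast, nutrient transporters, fetal endothelium, stroma and pericytes, yolk sac and endoderm, maternal decidua, uterine natural killer cells, myeloid cells and lymphocytes, and erythroid cells. Others covered folate and 1-carbon metabolism, DNA methylation and chromatin enzymes, paternally and maternally expressed imprinted genes, hypoxia and glycolysis, cell cycle, DNA damage and p53 response, sterol synthesis, steroid hormone synthesis, interferon response, inflammation and immediate early genes. The rest covered heat shock and unfolded protein response, oxidative phosphorylation, oxidative stress response, sex-linked transcripts and genes recalled from the published study of these samples. Of their 756 entries, 686 were measured.

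The groups, the lists, the tests, the alternative settings, apart from those added later, and the rule for named genes were chosen before the data were examined. The rule named, per direction, the 10 genes with the largest change among probes with an adjusted p under 0.05. Where fewer passed, it was filled up to 10 with the largest changes among probes with an unadjusted p under 0.01 whose groups do not overlap. In these steps a gene was represented by its probe with the smallest p. The rule also named up to 4 genes per list with an unadjusted p under 0.05. Cav1, Txndc16, Folr1, Slc19a1, Mthfr, Dnmt1, Igf2, H19, Cdkn1c and Phlda2 were named whatever their values, and Xist, Ddx3y, Uty, Kdm5d and Eif2s3y were given per placenta.

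Alternatives covered quantile and median scaling, normexp background correction with an offset of 50, the authors' table, other signal filters, each placenta left out in turn, the replicate number or slide row as a block, array weights, a trended robust variance and 1 probe per gene. Scores of Y-linked and of decidua transcripts as covariates, other thresholds, and the mean over a gene's probes were also used. The files hold no mean spot signal, so normexp was run on the median spot signal and median background in place of the planned mean. Slide or scan as a block was not run, since each had 1 level. Leaving out FD4 with FS3, leaving out FS1, FD3 and FD4, and using yolk sac or smooth muscle scores as covariates were added after the data were seen.

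The pipeline was tested on simulated data for this comparison, with 31185 probes drawn independently at the real means and spreads and 200 of them changed. At an adjusted p under 0.05, limma called 38.0% of the probes changed 2-fold and 74.0% of those changed 4-fold, with 7 false calls. With no change simulated there were 0 calls, and 5.10% of probes had an unadjusted p under 0.05. In a simulation of 14576 genes the 1 shifted list was called and no other, and a doubled spread in FD was recovered as a log2 ratio of 1.01. Genes of a list were drawn independently there, so camera's calls on correlated genes were not tested. Lists called in the real data had estimated correlations of 0.19 to 0.43. The number of arrays limits the precision: the median standard error of a log2 difference was 0.21.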

Results

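Gene expression was measured in placentas of fetuses at 18.5 days post coitum (dpc), carried by CD-1 females, an outbred stock, and sired by inbred C57BL/6 males. The males had been exposed through life to a folate-sufficient diet with 2 mg folic acid per kg (FS) or to a folate-deficient diet with 0.3 mg per kg (FD). Each group had 4 placentas from different litters and fathers. The share of spots well above background was 57.2%, 54.4%, 52.6% and 57.7% in FS1 to FS4, and 59.7%, 58.1%, 58.3% and 55.2% in FD1 to FD4. Levels are given on the log2 scale relative to the 75th percentile of the array.

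Transcripts of the Y chromosome were present in placentas of both groups. Ddx3y, a Y-linked RNA helicase gene, measured 0.64 and 0.84 in FS2 and FS3 and 0.54, 0.59 and 0.72 in FD1, FD2 and FD3, and was not well above background in FS1, FS4 and FD4. Eif2s3y lay between -1.45 and 0.65 and Uty between -3.79 and -2.68 in the same 5 placentas, a second Uty probe was not well above background on any array, and Kdm5d was well above background on 1 array. Xist, the RNA that coats the inactive X chromosome, measured 1.13, 1.07 and -0.52 in FS1, FS4 and FD4. It measured -2.60 in FS2 and -3.18, -3.11 and -4.59 in FD1, FD2 and FD3, and was not well above background in FS3.

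Transcripts of the yolk sac and of the maternal decidua also varied within groups. The mean of the yolk sac and endoderm list, centred over the 8 placentas, was -1.27 in FS1, -1.42 in FD3 and -1.78 in FD4, against 0.81 to 0.98 in the other placentas. The maternal decidua list, made of genes of the mother's uterine lining, measured -1.05 in FS3 and 0.98 in FS2. The mean correlation of FD4 with the other arrays across probes was 0.966, against 0.974 to 0.981 for the others. Correlations averaged 0.976 within groups and 0.977 between groups.

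The main comparison asked which transcripts differ in the placenta with the father's folate supply. The largest separated differences toward higher levels in FD were those of Tmem145, at 1.17 (SE 0.28), and Fancg, a member of the Fanconi anemia DNA repair complex, at 1.12 (SE 0.16). Grin2b, an NMDA receptor subunit, was not well above background on any FS array, and the background bound on its fold was 1.86 (limma adjusted p = 0.840). That bound leaves out sampling error and the choice of background correction. The log2 difference was 0.99 (SE 0.16) here, 0.12 to 0.19 with normexp and 0.34 in the authors' table. Bhmt, which remethylates homocysteine with betaine, differed by 0.80 (SE 0.18) and was well above background on 1 of 4 FS arrays and 4 of 4 FD arrays. Sgpp2, Dlg4, Tmem62, Plekha6, Kctd11 and Otog differed by 0.86, 0.86, 0.79, 0.77, 0.76 and 0.74. Of the 4 FS arrays, Dlg4 was well above background on 1, Fancg and Otog on 2, and Sgpp2, Plekha6 and Kctd11 on 3.

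The largest separated differences toward lower levels in FD were those of Ceacam10, an adhesion molecule of the carcinoembryonic antigen family, at -2.07 (SE 0.48), and Clec10a, a C-type lectin of macrophages, at -1.94 (SE 0.32). Cabs1, Pirt and Apol10b followed at -1.64, -1.53 and -1.51. Ngef, an exchange factor for Rho proteins, differed by -1.32, Fndc1 by -1.29, Ceacam2 by -1.23, the microtubule-associated Map1a by -1.22 and Fcmr, a receptor for immunoglobulin M, by -1.15. Of the 4 FD arrays, Map1a was well above background on 2, and Clec10a, Pirt, Fndc1 and Fcmr on 3. None of these 20 genes passed the adjusted threshold, their limma adjusted p values ranging from 0.742 for Fancg to 1.00. Each gene was represented by its probe with the smallest p. Other probes of the same gene gave 1.06 for Tmem145, 0.02 for Fndc1, -0.25 for Kctd11, 0.18 for Tmem62, 0.14 for Plekha6 and -0.51 for Map1a. For Kctd11, Tmem62 and Plekha6 the other probe was far brighter, with FS means of 2.34, 0.68 and 1.90 against -4.27, -3.65 and -4.02. The unadjusted limma p of these brighter probes was 0.318, 0.386 and 0.448.

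**Figure D1:**
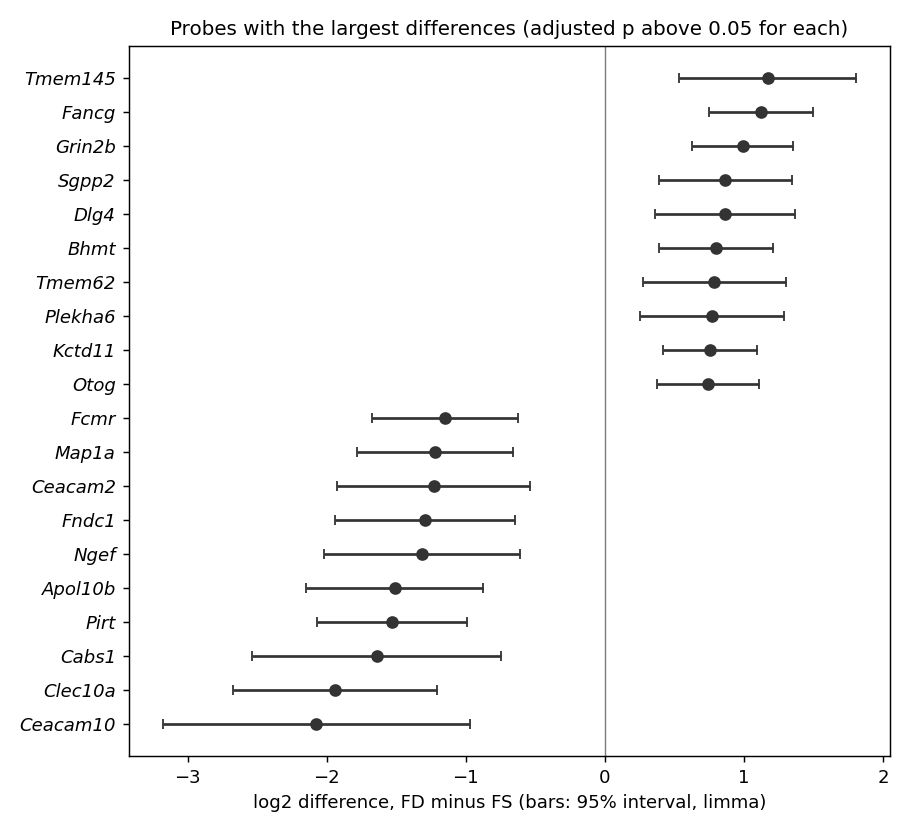
Log2 difference, FD minus FS, of the 20 genes with the largest separated differences, each by its probe with the smallest p. Points are limma estimates from 4 placentas per group and bars their 95% intervals. Estimates run from -2.07 for Ceacam10 to 1.17 for Tmem145, and none of the genes had an adjusted p under 0.05.

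With limma, 0 of 31208 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.621. An unadjusted p under 0.05 was found for 1160 probes, 645 higher and 515 lower in FD, where 1560 would be found with no difference at all. Of these, 509 also changed at least 1.5-fold, 287 higher and 222 lower, and they included 264 named genes. The groups did not overlap for 844 probes, or 2.70%, against 2.86% by chance. The 56.4% of the 509 that were higher became 41.5% of 135 and 46.3% of 136 with normexp correction at the 75th percentile or by quantiles, and 46.4% of 211 in the authors' table. The count was 1009 without FD4, 71.5% of it higher, and 765 without FS3. Over all alternatives the share higher ran from 36.9% with 1 probe per gene to 79.0% without FS1, FD3 and FD4, and it was 69.9% with array weights. Under normexp at the 75th percentile Tmem145 differed by 0.98, Fancg, Grin2b, Bhmt and Tmem62 by 0.24, 0.12, 0.049 and 0.19, and Sgpp2, Dlg4, Plekha6, Otog and Kctd11 by 0.12, 0.11, 0.12, 0.10 and -0.0090. Ceacam10, Clec10a, Cabs1, Pirt and Apol10b then differed by -1.02, -0.67, -1.03, -0.44 and -0.47, and Ngef, Fndc1, Ceacam2, Map1a and Fcmr by -0.997, -0.41, -1.09, -0.32 and -0.38.

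Cav1 and Txndc16 were recalled from the published study of these samples, so their list was chosen on these data and is not independent evidence. Cav1, the main coat protein of caveolae, measured -0.84 ± 0.24 (SD, n = 4) in FS and -1.59 ± 0.17 in FD, a difference of -0.75 with a 95% interval from -1.11 to -0.38. Txndc16, which encodes a thioredoxin domain protein, measured -0.28 ± 0.09 in FS and 0.07 ± 0.05 in FD, a difference of 0.35 with an interval from 0.10 to 0.60. For both genes the 4 FS and 4 FD placentas did not overlap. The unadjusted limma p was 0.00141 for Cav1 and 0.0125 for Txndc16. Adjusted over the list alone the limma p was 0.00281 and 0.0125, and over all probes it was 1.00 for both. The Cav1 difference was -0.47 and -0.44 under the 2 normexp settings and -0.48 with a smooth muscle score as a covariate.

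On the probe chosen for each gene, genes of folate uptake and use and of placental growth control differed by less than the standard error of the difference. The folate receptor Folr1 differed by -0.02 (95% interval -0.91 to 0.87), the reduced folate carrier Slc19a1 by -0.01 and the folate-cycle reductase Mthfr by 0.20. The sign of Folr1 turned under quantile scaling, normexp and the authors' table, and that of Slc19a1 under normexp and the authors' table. The maintenance methyltransferase Dnmt1 differed by 0.02, and the imprinted growth regulators Igf2, Cdkn1c and Phlda2 by 0.05, -0.10 and -0.13. Of these 7 genes only Cdkn1c kept its sign under every alternative run; Mthfr turned with the smooth muscle covariate alone (-0.18). The limma adjusted p was 1.00 for each. Other probes gave -0.13 for Folr1 and 0.10 for Mthfr, while a second Slc19a1 probe at 0.40 (SE 0.22) and another Mthfr probe at 0.19 (SE 0.18) exceeded their standard errors.

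**Figure D2:**
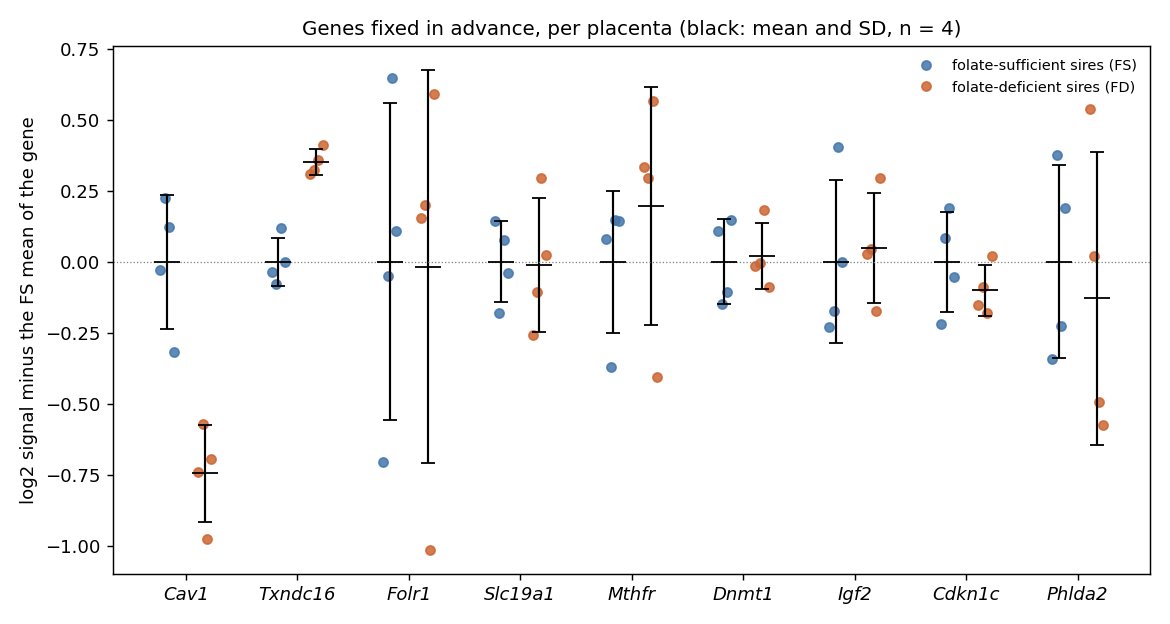
Log2 level of 9 genes chosen in advance, each placenta shown as a point relative to the FS mean, with the group mean and SD in black (n = 4). Cav1 and Txndc16 separate the groups, with differences of -0.75 and 0.35, and the other genes overlap. Cav1 and Txndc16 were recalled from the published study of these samples, so their separation is not independent evidence.

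Among the gene lists, that of stroma and pericytes had 20 of its 21 measured genes lower in FD, with a median of -0.64. The smooth muscle myosin Myh11 differed by -1.60, the collagens Col6a1 and Col1a1 by -1.45 and -1.33, the microfibril protein Fbn1 by -1.08 and the pericyte proteoglycan Cspg4 by -0.60. Col1a1 was named outside the rule for named genes. Of the list's genes, 7 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. The camera adjusted p was 7.35e-10 at the preset correlation, and the adjusted p = 0.975 with an estimated correlation. The exact permutation p of the list's mean was 0.114. The list's mean was 0.62, 1.09, 0.18 and -0.44 in FS1 to FS4, against -0.51 to -0.27 in FD. FS4 thus lay within the FD range, and with a smooth muscle score as a covariate the difference was 0.000902.

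Markers of uterine natural killer cells, maternal lymphocytes of the decidua, were lower in FD for 10 of 10 measured genes, with a median of -0.72. The granzymes Gzmd, Gzmf, Gzmc, Gzmg and Gzme, named outside the rule for named genes, differed by -1.42, -1.27, -1.19, -1.15 and -1.13. None of the genes had an unadjusted limma p under 0.05. The camera adjusted p was 0.00196, the adjusted p = 0.975 with an estimated correlation, and the exact permutation p was 0.143. The list's mean was 1.47 in FS1, between -0.27 and 0.37 in the other FS placentas, and between -0.68 and 0.23 in FD. The difference of means was -0.72. The call ended without FS1 (-0.35), without FS1, FD3 and FD4 (-0.49) and with the smooth muscle covariate (-0.33). With no signal filter, which had removed 10 of the 20 genes, the difference was -0.44.

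The yolk sac and endoderm list was lower in FD for 25 of 26 genes, with a median of -0.72. The plasma carrier proteins Ttr and Alb differed by -1.31 and -1.44, the apolipoprotein Apob by -1.15 and alpha-fetoprotein, Afp, by -0.71. These genes were named outside the rule for named genes. The camera adjusted p was 0.00338, the adjusted p = 0.975 with an estimated correlation, and the exact permutation p was 0.457. The placentas with low levels, FS1, FD3 and FD4, came from both groups. The difference of means was -0.66 over all placentas, and the call ended without FS2 (-0.46), FS3 (-0.49), FD3 (-0.30) or FD4 (-0.18). It also ended with no filter (-0.66), the smooth muscle covariate (-0.76), array weights (0.15), without FD4 and FS3 (-0.0071) and without FS1, FD3 and FD4 (0.067), and the difference was larger without FS1 (-1.20), FD1 (-1.10) or FD2 (-1.07).

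Of the fetal endothelium genes 20 of 25 were lower in FD, with a median of -0.13; the transcription factor Erg differed by -0.68. The camera adjusted p was 0.00338, the adjusted p = 0.975 with an estimated correlation, and the exact permutation p was 0.400. The difference of means was -0.16, and the call ended without FS2 (-0.12), FS3 (-0.08) or FD3 (-0.05), while the difference was -0.26 without FS4. The call also ended with no filter (-0.16), array weights (-0.022), the yolk sac covariate (-0.12) and the smooth muscle covariate (0.077), without FD4 and FS3 (-0.13) and without FS1, FD3 and FD4 (-0.11). Interferon response genes were higher in FD for 23 of 33, with a median of 0.12. The peptide transporter Tap1 and the RNA sensor Ddx58 differed by 0.66 and 0.28, and a second Ddx58 probe by 0.13. The camera adjusted p was 0.00626, the adjusted p = 0.975 with an estimated correlation, and the exact permutation p was 0.371. The difference of means was 0.12, and the call ended without FS3 (0.04) or FD2 (0.11), without FD4 and FS3 (-0.018) and without FS1, FD3 and FD4 (0.0057). The difference was 0.06 without FD4 and 0.18 without FS2 or without FD1, and ranged from -0.018 to 0.20 over all settings.

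These 5 of 26 lists were called by camera at the preset correlation. None of the calls held with an estimated correlation, and fry called 0 lists. In 0 of the 26 lists did a gene pass when adjusted over the list alone.

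**Figure D3:**
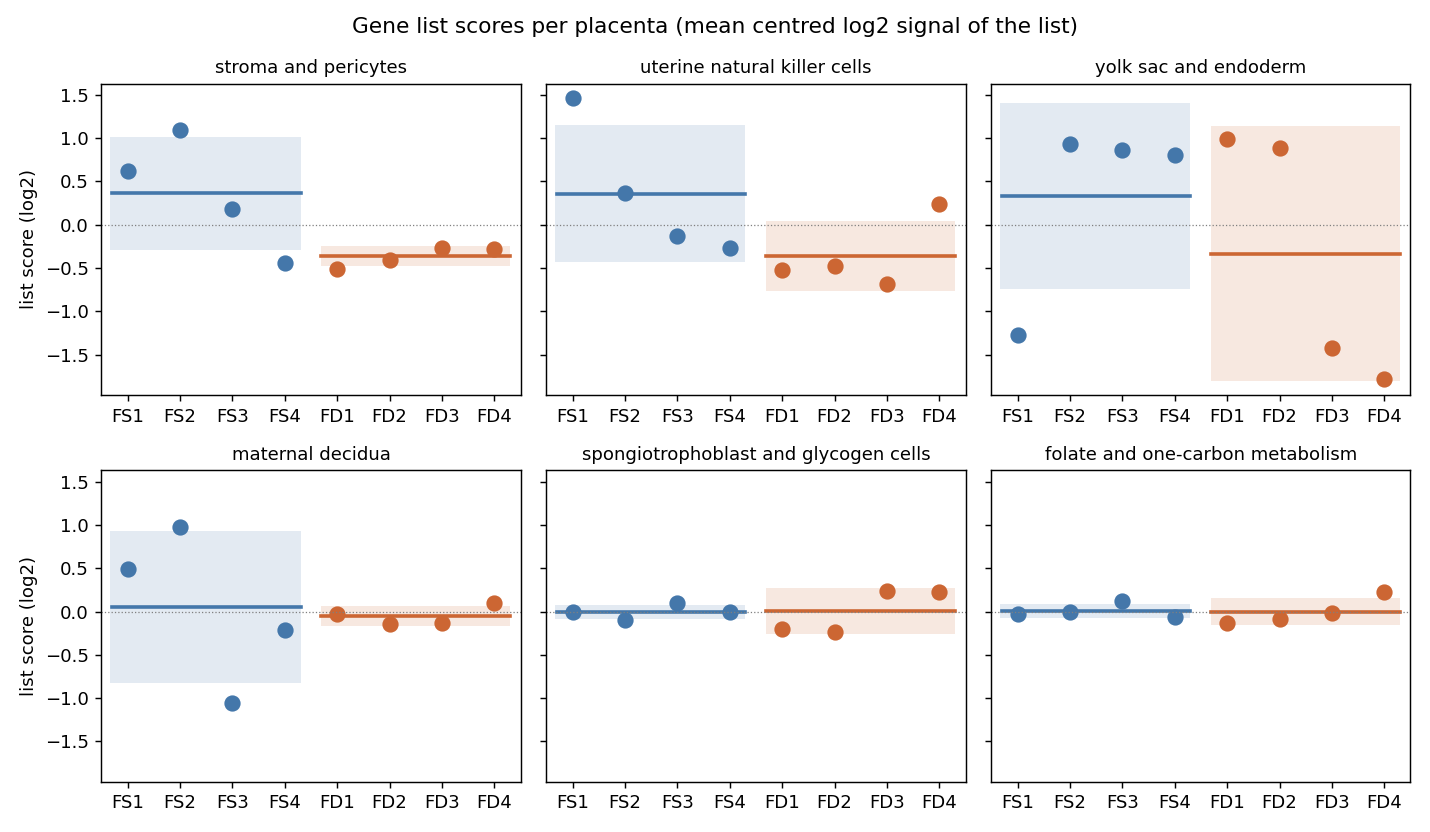
Mean centred log2 level of 6 gene lists per placenta, FS and FD side by side; points are placentas, lines group means and shading the SD (n = 4). Yolk sac and endoderm genes were low in FS1 (-1.27), FD3 (-1.42) and FD4 (-1.78), and stroma genes were high in FS1 (0.62) and FS2 (1.09).

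Lists of the placental layers gave no call in this comparison. The median was -0.01 for spongiotrophoblast and glycogen cells (camera adjusted p = 0.900), 0.12 for trophoblast giant cells (0.103) and 0.01 for labyrinth syncytiotrophoblast (0.942). Giant cell genes, with a difference of means of 0.19, were called higher by camera under quantile scaling (adjusted p = 0.0210), normexp (0.0145 and 0.00520) and in the authors' table (0.00332), and without FS3 (0.30) or FD2 (0.26). Over all settings their difference of means ranged from -0.084 to 0.30. Their adjusted p ranged from 0.00152 to 0.975, the latter with an estimated correlation. Nutrient transporters had a median of 0.04 (0.900); the amino acid transporter Slc38a2 measured 0.48 higher and the calcium-binding S100g differed by -0.77, on its second probe by -0.75. The maternal decidua list had a median of -0.05 (0.408), with the microfibril gene Mfap4 at -1.48. Myeloid cells and lymphocytes had a median of -0.07 (0.881), with the macrophage mannose receptor Mrc1 at -0.65. Erythroid cells had 0.02 (0.900), with Tal1 at -0.36 and Kel at -0.77. With the smooth muscle covariate Slc38a2, S100g, Mfap4, Mrc1, Tal1 and Kel differed by 0.54, -0.51, -0.74, -0.31, -0.42 and -0.82.

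Folate and 1-carbon metabolism genes had a median of -0.01 (camera adjusted p = 0.900), and Bhmt was the only one of 44 with an unadjusted limma p under 0.05. DNA methylation and chromatin enzymes had a median of -0.01 (0.900). Paternally expressed imprinted genes had a median of -0.06 (0.881). Their mean difference was -0.14, with an exact permutation p of 0.0286, the smallest these relabellings can give, and of 0.743 when adjusted over the lists. The list's mean was -0.26 in FD4, where Mest was low, and without FD4 the difference was -0.076. With the smooth muscle covariate the difference was -0.19, with a camera adjusted p of 0.0441 at the preset correlation. Maternally expressed imprinted genes had a median of -0.10 (0.883).

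Among stress and signalling lists the medians were -0.09 for oxidative stress response (camera adjusted p = 0.0907), 0.07 for heat shock and unfolded protein response (0.646), -0.03 for immediate early genes (0.900) and 0.04 for inflammation (0.900). Hypoxia and glycolysis had 0.02 (0.883), with the oxygen sensor Egln1 at 0.37. DNA damage and p53 response had -0.05 (0.900), with Parp1 at 0.50 and Atm at -0.37, while a second Atm probe gave 0.25. With normexp by quantiles Egln1 differed by 0.11, Atm by -0.14, Kel by -0.40, Erg by -0.31, Cspg4 by -0.36, Mrc1 by -0.43 and Tal1 by -0.23, and with normexp at the 75th percentile Egln1 differed by 0.053 and Tap1 by 0.44. Oxidative phosphorylation, steroid hormone synthesis, sterol synthesis and cell cycle had -0.02, -0.07, -0.04 and 0.02, each with 0.900. Median, mean and camera's direction differed in sign for spongiotrophoblast (mean 0.01, camera lower), inflammation (mean -0.02, camera higher) and cell cycle (mean -0.01, camera higher). Camera's direction was also opposite to the median and mean for folate metabolism, DNA methylation and erythroid genes. Leaving out 1 placenta brought a camera call at the preset correlation for 5 more lists. An estimated correlation was not run on these reduced sets. The calls were maternal decidua (-0.47) and myeloid cells and lymphocytes (-0.23) without FS3, and oxidative phosphorylation (-0.17) without FD4. The others were oxidative stress response without FS1 (-0.16) or FD4 (-0.17), and heat shock without FD2 (0.11). The maternal decidua difference was -0.10 over all placentas and turned to 0.20 without FS2, 0.043 without FS1, 0.010 without FS1, FD3 and FD4 and 0.52 with the smooth muscle covariate. The sex-linked list had 4 measured genes and received no list test.

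The spread of expression within groups was compared over 14576 genes. The median SD over genes was 0.20 among FS and 0.28 among FD placentas, a log2 ratio of 0.49 with an exact two-sided permutation p of 0.571. Without FD4 the ratio was -0.22.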

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

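Of the tests in this part, that of a second endoderm list had its bounds set down before its result was seen, on genes listed after the data were seen, and all others were chosen after the results were seen. Of 144 groups of 4 values, 14 held a value far from the other 3 of its group, with a gap past the 95% critical value of Dixon's test; chance gives 7.2, or about 1 in 20 groups. FD4 accounted for 4 of them and FS3 for 3. Among the list means, yolk sac and endoderm was low in FS1 (-1.27), paternally expressed imprinted genes were high in FS3 (0.18) and low in FD4 (-0.26), and hypoxia and glycolysis (0.21) and cell cycle (0.41) were high in FD4. Among single genes, Pirt was high in FS1 (-2.29), Apol10b in FD3 (-3.90), Erg in FS3 (-1.63), Mrc1 in FD4 (-0.79), Kel in FS3 (-0.82) and Ddx58 in FS4 (2.75). Map1a was low in FS4 (-3.97), Cspg4 in FD1 (-1.68) and Mthfr in FS2 (2.63).

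Yolk sac transcripts were low in FS1, FD3 and FD4: Afp, which encodes alpha-fetoprotein, measured 7.52, 7.59 and 7.14 there and 9.89 to 10.14 in the other 5 placentas. By level, 3 placentas lay on the side of the other group: FS1 among the low ones, and FD1 and FD2 among the high ones. The diet of the father alone thus does not sort the placentas into low and high. The low placentas were picked from these same values, so the count restates the pattern and is not a separate test. A uniform difference of signal between arrays was removed beforehand by the scaling of each array, so it could not be tested. After scaling, the spongiotrophoblast list lay at most 0.24 from its mean on these arrays. That argues only against a fall shared by all transcripts after scaling. A second list of 20 visceral endoderm genes was written after the data were seen, with none of them in another list. Of these genes, 90.0% had the same 3 placentas lowest, where chance gives 1.79% for a single gene. Such genes vary together (estimated correlation 0.35 in the first list), and the 3 placentas were picked from the first list. The match is thus not independent evidence and does not separate the amount of tissue from a change of expression. A candidate explanation is the amount of yolk sac left on the sampled placenta, and a part played by diet stays open.

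Mest, a paternally expressed imprinted gene, measured -2.34 in FD4 and 2.90 to 3.76 in the other placentas, and was chosen after its values were seen. A fall as deep as that of Mest was not found in other named genes well above background on the other 7 arrays. Probes without a name were not counted in this test. Of 17540 named probes, 0.0114% lay as far below the other arrays in FD4, and both of these probes belong to Mest. The scaling of each array removes a uniform loss of signal, and a smaller loss would not reach this bound, so neither was tested. By the smaller bound given under other observations, 1087 probes lay below every other array in FD4, against 21 to 254 for the others. Of these 1087 probes, 198 were named. Gabrd, also picked after its values were seen, fell by 4.13 below the lowest other placenta and was not above background in FD4. Of the 3 Mest probes, 2 fell by 5.24 and 5.18 below the lowest other placenta and the other was not above background in FD4; a variant stays open, since whether the probes overlap is not known here. A fall of paternally expressed genes in general was argued against: the other 29 measured genes had a median fall of -0.012 (SD 0.55) in FD4 below the mean of the other placentas, against 5.57 for Mest, and a largest gap of 1.01 below the lowest other placenta, though 8 of the 29 were lowest in FD4 and a smaller general fall stays open. A loss of the active Mest copy in this placenta may be considered beside these, but was not tested. The neighbours of Mest, Klf14 (0.10) and Copg2 (1.30 and 1.82), were highest in FD4.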

How the results depend on the processing

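Leaving out FD4 with FS3, leaving out FS1, FD3 and FD4, and the yolk sac and smooth muscle covariates were chosen after the data were seen; the other alternatives were planned. The count of probes with an adjusted p under 0.05 in limma was 0 under every alternative run, adjusted thresholds of 0.10 and 0.25 included, with 1160 at an unadjusted p under 0.05. Signal over background limits the dim genes, whose differences normexp with an offset of 50 draws toward 0 by construction.

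The count of 509 probes became 135 and 136 with normexp (75th percentile and quantile), 211 in the authors' table, 1518 with no filter, 314 with the filter on all 8 arrays, 1191 with array weights and 217 with 1 probe per gene. It became 1142 without FD4 and FS3 and 1679 without FS1, FD3 and FD4. It was 1160 with no fold minimum, 151 at 2-fold and 150 at an unadjusted p under 0.01, fewer or more by construction. Leaving out 1 placenta gave 455 to 1009, with 765 without FS3 and 1009 without FD4. For the other changes the cause was not tested.

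The 5 called lists became 3 with no filter, 2 without FS1, FD3 and FD4, 3 with the yolk sac covariate and 0 with an estimated correlation. The yolk sac covariate is the mean of the yolk sac list itself, so that list lost its call by construction. Fetal endothelium was the other list that lost its call there. With the smooth muscle covariate the called lists were 4, 3 higher and 1 lower, the lower being paternally expressed imprinted genes. Of the 5 only interferon was among these 4. Leaving out 1 placenta gave 3 to 6, with 3 without FS2 and 3 without FD3. The spread ratio of 0.49 ranged from -0.22 (without FD4) to 0.69 when 1 placenta was left out, and was -0.049 without FD4 and FS3 and -0.93 without FS1, FD3 and FD4. Of 1197 values of 45 named genes, 1 turned among genes with an unadjusted p under 0.05, Kctd11 with normexp (-0.00902). Of the called lists, stroma turned to 0.000902 and endothelium to 0.077 with the smooth muscle covariate, yolk sac to 0.15 with array weights and 0.067 without FS1, FD3 and FD4, and interferon to -0.018 without FD4 and FS3. Of 700 values of the lists, 31 lost a call and 23 gained one, 7 of these among trophoblast giant cells. With the smooth muscle covariate 2 lists gained one with their mean turned, cell cycle (-0.0081 to 0.25) and oxidative phosphorylation (-0.022 to 0.14). The cause was not tested.

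With the replicate number as a replicate block, the counts were 0, 536 and 5. Deviations of same-numbered placentas correlated with r of -0.18, 0.06, -0.14 and -0.10 across probes, and 1 of 4 FS placentas matched its own number best. No pairing by number was detected, though so few placentas cannot exclude one.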

Other observations

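All tests in this part were chosen after the results were seen, and the bound for the Cav1 test was changed once its value was known and then set back to its first form. Apart from the comparisons, granzyme and decidual transcripts differed strongly between single placentas. Gzme measured 4.69 in FS1, 3.21 in FS2 and 3.31 in FD4, and 1.06 to 2.20 in the others. Prl8a2, a prolactin family gene of the decidua, measured 2.48 in FS3 and 5.75 to 8.28 in the others. FD4 had 1087 probes lying over 1 log2 unit below every other array, against 21 to 254 for the others. These made up 8.63% of the probes known only by a genomic position and 1.04% of the named probes. These genes were chosen after their values were seen.

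Stroma and smooth muscle transcripts were high in FS1, FS2 and FS3; the smooth muscle actin Actg2 measured 4.24, 5.98 and 4.23 there, 1.61 in FS4 and 1.06 to 2.65 in FD. Maternal uterine muscle stays open: in FS3 Xist was not above background while a second smooth muscle list stood at 0.27 against at most -0.12 in FD, but the maternal transcripts Gzme (2.20) and Prl8a2 (2.48) were above background there too. The diet of the father stays open, since the exact permutation p of the stroma list was 0.114. For the second list, with 12 of 14 genes lower in FD, the exact permutation p was 0.0571. That list was written after the data were seen, so its result is not independent evidence. A lower share of smooth muscle as the whole cause of the Cav1 difference stays open. With the second list's score as a covariate the difference went from -0.75 (SE 0.16) to -0.48 (SE 0.19). That is over 2 standard errors below 0, with an unadjusted limma p of 0.0417. The value thus met the restored bound for a result against the share of muscle as the whole cause. The score measures the share of muscle only imperfectly, so a difference that remains does not exclude it as the whole cause. In FS4 the score (-0.25) lay within the FD range (-0.38 to -0.12). Cav1 there measured -1.16 against -1.82 to -1.41 in FD, though 1 placenta excludes nothing.

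Chance could not be excluded for the count of 509 probes or for that of the 5 called lists by regrouping the placentas. The count of 509 was reached by 20 of 35 splits, the highest being 2047, and the 5 called lists by 29 of 35, the highest being 14. The split with 2047 probes, several times the real count, exchanged FS1 and FD4 between the groups and kept the other 3 placentas of each together. It was singled out as the highest of the splits, so its size alone does not show a structure of the placentas, which was not tested. For probes with an adjusted p under 0.05 the real count was 0 and the highest other 1; a count of 0 is reached by all 35 splits whatever the data, so this decides nothing.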
